A study of Pelophylax nigromaculatus with 27 samples.

How the data were processed

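Messenger RNA was measured in brain, liver and muscle of adult black-spotted pond frogs (Pelophylax nigromaculatus), a cultured species that develops a meningitis-like disease with a twisted neck (torticollis) and, in some animals, clouded lenses (cataracts). The labels place every library in 1 of 3 health states: healthy (H), torticollis (T), and torticollis with cataracts (TC). The T label does not mention cataracts. Each tissue had 9 libraries, 3 per health state, which made 27 libraries in 9 groups. Per the labels' protocols, RNA was extracted with Trizol, poly-T selected and fragmented, and paired-end reads were generated on an Illumina HiSeq instrument. The labels do not state whether the 3 libraries of a group came from 3 frogs, so p-values measure the spread between these libraries.

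The authors deposited a single table of FPKM values (fragments per kilobase of transcript, scaled to library size) for 306785 assembled unigenes, per the file headers. The unigene identifiers have the form that the Trinity assembler writes. The assembler version, the aligner, the counting program and any filter are not given in the sources used here. The table does not pair identifiers with gene names, and no annotation was used here, so unigenes are reported by identifier and length. Near-identical unigenes can split the reads of 1 gene, and a gene can be represented by several unigenes. No column of sample values was left unused (0 columns).

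Depth was recovered from the FPKM values themselves. The values of a unigene were whole multiples of a step set by its length and the library total, and 100% of the 4077770 values above 0 were whole counts within a tolerance of 0.001 counts. The recovered library totals ranged from 31340952 to 37806798, and unigene lengths from 201 to 34414 bases with a median of 360. On simulated data the same procedure returned 99.961% of unigenes exactly and all 27 totals. At these totals 1 count on a unigene of 1000 bases is worth 0.0265 to 0.0319 FPKM, so a count of 0 allows up to 3 counts, or 0.0794 to 0.0957 FPKM, and this covers counting error only.

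Each tissue was fitted separately with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), using empirical Bayes moderation with an intensity trend and 1 mean per health state. Unigenes with an FPKM of at least 1 in at least 3 of the 9 libraries of the tissue were tested: 94030 in brain, 40090 in liver and 28468 in muscle. The contrasts were T minus H, TC minus H and TC minus T, with a moderated F-test of any difference among the 3 states. Calls had a Benjamini-Hochberg adjusted p below 0.05. Changes are on the log2(FPKM + 1) scale, which understates the change of low unigenes. A fit over all 27 libraries tested the interaction of tissue and health state in the 20468 unigenes that passed the filter in all 3 tissues, and compared TC minus H between pairs of tissues.

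The tests, samples, alternatives and the naming rule were fixed before the data were examined. Because the table holds no gene names, the preset gene lists could not be applied. The naming rule then allowed at most 2 unigenes that rose and 2 that fell per comparison, those with the largest change among called unigenes whose groups did not overlap. For the tissue differences the same rule was applied without the condition on overlap, a choice made after the data were seen.

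In place of gene lists, 4 groups of unigenes were built for each tissue from mean FPKM per tissue, also after the data were seen. A tissue's own enriched group held unigenes at least 8-fold (3 on the log2 scale) above both other tissues. Groups enriched in another tissue held unigenes at least 8-fold above the remaining tissue, with a log2 level of at least 4 and no condition on the tissue under test. The group even across tissues spanned less than 1 on the log2 scale with at least 5 FPKM in every tissue. They were tested with camera in limma at the preset inter-gene correlation of 0.01 and with an estimated correlation, and the mean level per library was compared by an exact permutation test over 280 splits. The p-values of the 36 camera tests and of the 12 permutation tests were each adjusted by the Benjamini-Hochberg method.

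RNA of 1 tissue found in libraries of another was estimated as the median, over the 100 most abundant unigenes more than 20-fold above both other tissues, of the FPKM in the library as a share of the mean in the source tissue. Simulated additions of 0.05% and 0.5% of the liver profile to a healthy brain library were returned as 0.05% and 0.5%. The addition was the mean liver profile without noise, so this checks the calculation and not whether 1 share holds for every transcript. The interaction and contrast fits were tested on simulated data with 200 changed unigenes. In brain 54% of 4-fold and 98.5% of 16-fold changes were recovered, with 7 and 29 unchanged unigenes called. In liver 2% and 94.5% were recovered, with 1 and 4 unchanged, and in muscle 15.5% and 95.5%, with 1 and 18. The interaction test recovered 193 of 200 16-fold changes (96.5%) and also called 51 unchanged unigenes. False calls thus exceeded 5% of calls in every simulation except liver at 16-fold and muscle at 4-fold. The simulated errors were independent between unigenes. Deviations that many unigenes of a library share were not simulated and could add false calls.

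Titles number the libraries 1 to 9 in each tissue, and the labels do not state that a number is 1 frog. Deviations from the group means were correlated between tissues for equal numbers. Between brain and liver all 9 correlations exceeded 0.1 (0.149 to 0.403) and each of the 9 libraries correlated best with its own number, so the numbers were taken to pair brain with liver. For brain with muscle and for liver with muscle 6 of 9 exceeded 0.1, and those tissues were not treated as paired.

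Alternatives were a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM, median-of-ratios rescaling, leaving out each library, fits of 2 groups and the library number as a block. Added after the data were seen were voom in limma on the recovered counts and subtraction of the estimated share of other tissues. For differences between tissues, leaving out each library number and rescaling the tissue pairs were also added then. After the subtraction, camera was run at the preset correlation but without the intensity trend used in the other camera tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, and data were handled with numpy 2.4.6, pandas 2.3.3 and, in R, version 1.17.8 of the data.table package.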

Results

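Gene expression in 3 tissues, brain, liver and muscle, was set side by side for healthy frogs (H), frogs with torticollis (T) and frogs with torticollis and cataracts (TC), to describe the molecular changes that accompany the disease. Each group had 3 libraries of 31340952 to 37806798 counts, which may be reads or fragments. Brain expressed the most unigenes at 1 FPKM or more, 86182 ± 5241 (SD, n = 3) in healthy frogs, 77651 ± 5821 in T and 84695 ± 3623 in TC. Healthy liver expressed 39047 ± 5385, against 30851 ± 2546 in T and 30207 ± 1332 in TC liver (SD, n = 3). Muscle expressed 21774 ± 1679, 24035 ± 2072 and 26239 ± 7304 unigenes in H, T and TC. The 10 most abundant unigenes took 2.77 to 5.37% of the counts in brain, 11.4 to 15.3% in liver and 13.7 to 22.8% in muscle.

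The 3 TC brain libraries lay apart from the other 6 on the first component, at -102 to -111, against -29.0 to 101 for H and T. Across unigenes the TC brain libraries correlated with each other at a mean r of 0.885, and with healthy brain libraries at 0.842. In liver, healthy library 1 correlated at 0.724 and 0.718 with healthy libraries 2 and 3, which correlated with each other at 0.905. It lay at -110 on the first liver component, beside TC library 7 at -113. In muscle, TC library 7 lay farthest out, at -134. These correlations are across unigenes, which are not independent replicates.

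**Figure D1:**
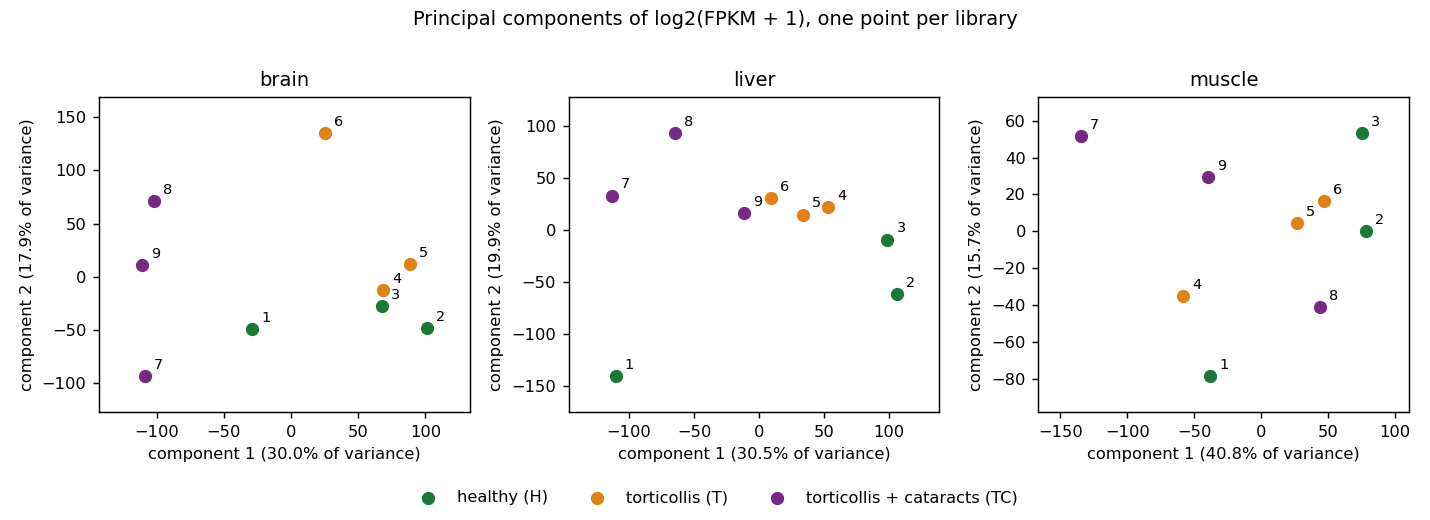
Principal components of log2(FPKM + 1) in brain, liver and muscle, 1 point per library, coloured by health state and numbered as in the titles; axes give the component score and the share of variance. On component 1 the 3 TC brain libraries lie between -111 and -102, and healthy library 1 lies on the TC side of the other healthy libraries in all 3 tissues.

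Brain of TC frogs was compared with healthy brain first. TC brain differed from healthy brain in 689 of 94030 unigenes, of which 633 were higher and 56 lower. TRINITY_DN40060_c0_g2 (2036 bases) rose from 6.57 ± 9.15 FPKM in healthy brain to 174 ± 44.1 in TC brain (SD, n = 3), a log2 change of 5.23 ± 0.698 (SE, limma, adjusted p = 0.0188), with 18.5 ± 8.87 in T brain. TRINITY_DN36517_c0_g1 (477 bases) rose from 20.9 ± 33.2 to 316 ± 152 FPKM (log2 change 5.23 ± 0.998 (SE), limma adjusted p = 0.0463). T brain was at 104 ± 45.6 FPKM, with T library 6 (146) above TC library 8 (145). The means of this unigene did not rise in liver or muscle. They were 293 ± 438 and 269 ± 372 FPKM in H and TC liver and 4670 ± 8077 and 443 ± 360 in H and TC muscle (SD, n = 3). In both tissues this rests on healthy library 3, at 797 FPKM in liver and 13996 in muscle. Healthy libraries 1 and 2 were at 75.8 and 6.76 FPKM in liver and 3.98 and 10.5 in muscle. TRINITY_DN60553_c2_g1 (310 bases) fell from 38.3 ± 11.2 FPKM and 1227 counts in healthy brain to 1 count in the 3 TC brain libraries together (limma adjusted p = 6.59e-05), while T brain held 32.9 ± 8.35 FPKM. TRINITY_DN70418_c6_g1 (393 bases) fell from 14.5 ± 6.09 FPKM and 586 counts to 0 counts in TC brain (limma adjusted p = 0.00151), and also had 0 counts in all 3 T brain libraries and in the 6 T and TC liver libraries, against 67 counts in healthy liver. In muscle it had 47, 24 and 20 counts in H, T and TC. The 24 were all in T library 4 and the 20 all in TC library 9.

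The brain unigenes that rose in TC were mostly unigenes that liver also expressed. Of the 633, 499 (78.8%) had a mean of at least 1 FPKM in liver, against 30.4% of the other tested unigenes (Fisher's exact test, two-sided, odds ratio 8.51, p = 4.93e-138, across unigenes, which are not independent). Of the 56 that fell, 3 did. In muscle 47.55% of the risers had a mean of at least 1 FPKM, against 23.27% of all tested unigenes. The excess was thus not particular to liver. The risers were also longer (median 711 against 526 bases). In liver, 382 of the 531 risers that could be tested there were higher in TC than in healthy libraries, with a median log2 change of 0.43 against -0.28 for all liver unigenes. The mean log2 level of the 633 was 3.38 in healthy liver library 1, above the 3 TC livers (3.05 to 3.23), and 2.46 and 2.25 in healthy libraries 2 and 3, so the rise in liver rests on those 2. T liver libraries ranged from 2.28 to 3.05. In muscle 282 of 295 were higher, with a median of 0.87 against 0.25, but TC library 7 stood apart at a mean log2 level of 2.31. TC libraries 8 and 9 were at 0.81 and 1.14, against 0.68 to 0.86 in healthy muscle. The set moved up relative to other unigenes in both tissues at the preset correlation of camera (adjusted p = 5.89e-22 and 1.1e-13) and in neither with an estimated correlation (adjusted p = 0.409 and 0.501 with an estimated correlation). Brain and liver share library numbers that pair them, so the liver values are not separate evidence for the rise of this set. The numbers may pair muscle too, so the muscle values may not be separate evidence either.

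The count of 689 varied widely with the settings: 17 at a pseudocount of 0.1 (13 higher and 4 lower), 151 with no filter, 10 with the 5 FPKM filter, 40 in a fit of the TC and H libraries alone, and 0 with voom on recovered counts. It was 2270, 19 and 11 without healthy brain libraries 1, 2 and 3, 153, 100 and 191 without T libraries 4, 5 and 6, and 287, 31 and 19 without TC libraries 7, 8 and 9. TRINITY_DN60553_c2_g1 was called without any 1 brain library (limma adjusted p at most 0.00133). TRINITY_DN40060_c0_g2 was not called without healthy libraries 2 or 3 or TC libraries 8 or 9 (limma adjusted p = 0.102, 0.107, 0.0812 and 0.115). TRINITY_DN36517_c0_g1 was called only without healthy library 1 (limma adjusted p = 0.00033), with limma adjusted p = 0.194 and 0.179 without healthy libraries 2 and 3, 0.074, 0.0709 and 0.0683 without T libraries 4, 5 and 6, and 0.108, 0.129 and 0.199 without TC libraries 7, 8 and 9. TRINITY_DN70418_c6_g1 was called without any 1 T or TC library and fell below the filter without any 1 healthy library.

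**Figure D2:**
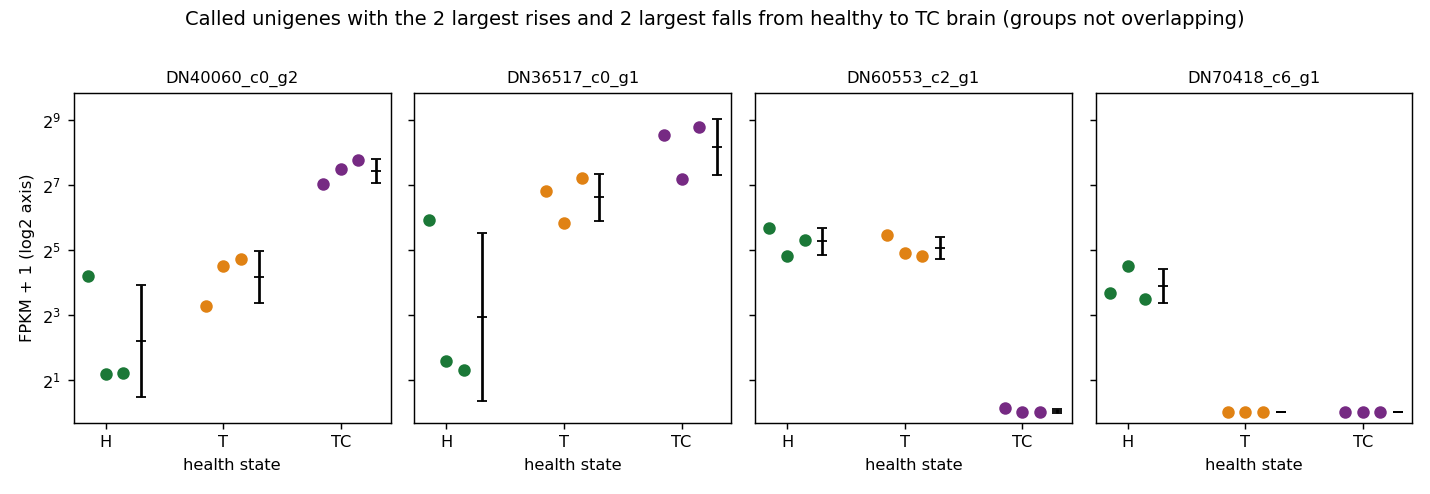
FPKM + 1 on a log2 axis in each brain library for the 2 unigenes with the largest rises and the 2 with the largest falls from healthy to TC brain, among called unigenes whose groups did not overlap, with the mean ± SD of the log2 values of the 3 libraries beside the points of each health state. TRINITY_DN40060_c0_g2 and TRINITY_DN36517_c0_g1 rose in TC, with T means between those of H and TC. TRINITY_DN60553_c2_g1 fell in TC, and TRINITY_DN70418_c6_g1 had 0 counts in T and TC.

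Unigenes were next grouped by their levels across tissues; in brain, liver-enriched means at least 8-fold above muscle and muscle-enriched at least 8-fold above liver, whatever the level in brain. In TC against healthy brain, 72 of the 917 liver-enriched unigenes rose and 0 fell, with a median log2 change of 0.45 against -0.08 for the others (camera adjusted p = 1.12e-21; adjusted p = 0.177 with an estimated correlation). The mean log2 level of this group was 2.57 ± 0.489 in H, 2.61 ± 0.246 in T and 3.47 ± 0.127 in TC brain (SD, n = 3; exact permutation p = 0.0429, adjusted p = 0.288 over 12 tests). Of the 5675 brain-enriched unigenes 10 fell and 2 rose, with a median of -0.32 against -0.05 (camera adjusted p = 4.18e-12; adjusted p = 0.507 with an estimated correlation). Of the 994 unigenes even across tissues 15 rose, with a median of 0.33 (camera adjusted p = 1.91e-20; adjusted p = 0.399 with an estimated correlation). Members of every group had passed the brain filter, which a unigene near 0 in healthy brain can do through the TC libraries alone. The 446 muscle-enriched unigenes had a median of 0.03 (camera adjusted p = 0.206), and 3 of them rose. Across the 3 tissues 22 of 36 such tests passed at the preset correlation and 0 with an estimated one. The exact permutation test of the library means passed in 0 of the 12 groups of the 3 tissues after adjustment (adjusted p at least 0.288), and 1 of 12 had an unadjusted p below 0.05.

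Transcripts of liver were also present at a low level in TC brain. The 100 most abundant liver-specific unigenes had a median share of 0.093%, 0.0325% and 0.0666% of their liver level in TC brain libraries 7, 8 and 9, against 0 to 0.0056% in the 6 H and T brain libraries. All 100 were higher in TC than in healthy brain, with a median of 5.36 FPKM against 0.106. In muscle the same share was 0.645% in T library 6, 0.051% and 0.0166% in T libraries 5 and 4, 0.0393% in TC library 7, and at most 0.00978% in the other 5. Muscle transcripts made up 0.0561% of their muscle level in healthy brain library 2 and 0.0945% in TC brain library 9. Brain transcripts stood at 0.0712 to 0.2405% of their brain level in the muscle libraries, and at 0.0712 to 0.0811% in the healthy ones. A share of this size thus does not by itself mean carried RNA, and low expression in the tissue itself was not tested. After subtraction of these shares, a step added after the data were seen, 19 liver-enriched unigenes rose in TC brain in place of 72 and the median of the group was 0.35. The total in brain was then 517 (471 higher and 46 lower), all of them among the 689, and TRINITY_DN36517_c0_g1 no longer passed (limma adjusted p = 0.0531), although its log2 change did not shrink (5.42 ± 1.05 after and 5.23 ± 0.998 before, SE).

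**Figure D3:**
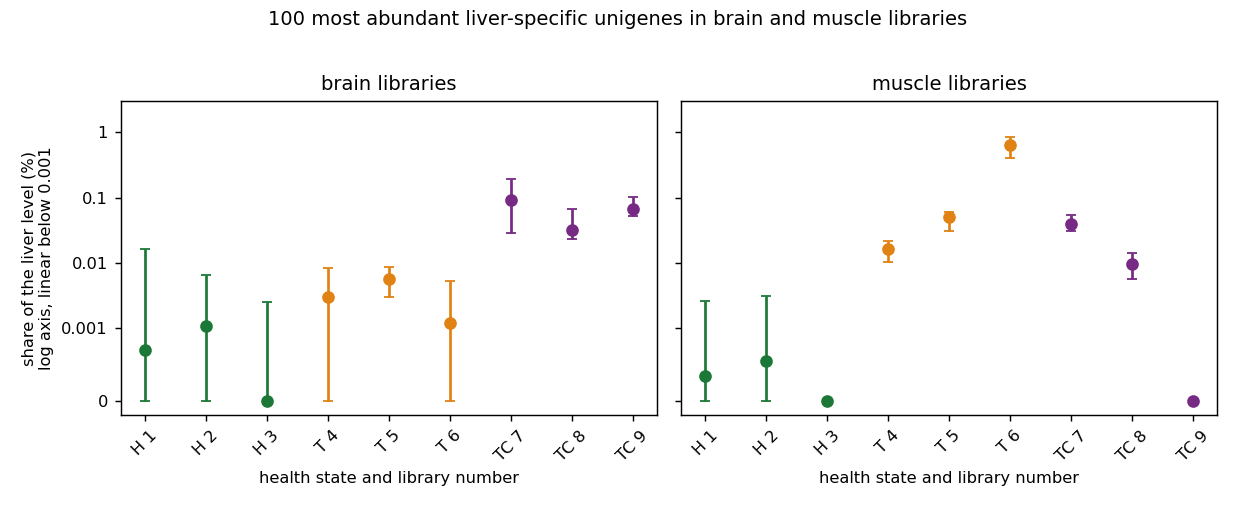
FPKM of the 100 most abundant liver-specific unigenes in each brain library (left) and muscle library (right) as a percentage of their mean liver FPKM, on a log axis that is linear below 0.001%. Points are medians and bars the interquartile range over the 100 unigenes. TC brain libraries lie at 0.0325 to 0.093%, and muscle T library 6 at 0.645%.

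TC brain was then set against T brain, which compares frogs labelled torticollis with cataracts with frogs labelled torticollis alone. In TC brain 1023 unigenes were higher and 73 lower than in T brain, and 470 of the 633 that rose against healthy brain were also called here. TRINITY_DN54786_c2_g2 (730 bases) rose from 1.52 ± 1.42 to 188 ± 97.8 FPKM (SD, n = 3; log2 change 6.24 ± 1.14 (SE), limma adjusted p = 0.0364), and TRINITY_DN45401_c1_g2 (740 bases) from 0.786 ± 1.17 to 92.7 ± 37.3 FPKM (log2 change 5.83 ± 1.14 (SE), limma adjusted p = 0.0415). TRINITY_DN60553_c2_g1 fell here too (limma adjusted p = 1e-04), as did TRINITY_DN66054_c0_g1 (280 bases), from 13.9 ± 3.67 FPKM and 422 counts in T to 0 counts in TC (limma adjusted p = 0.0345). Healthy brain library 1 lay toward TC for 3 of these: the first 2 were at 39.4 and 37.7 FPKM there and at most 0.159 in healthy libraries 2 and 3, and TRINITY_DN66054_c0_g1 had 0 counts there against 76 and 69. Liver-enriched unigenes moved up here too, 72 rising and 1 falling (median 0.52 against 0.07, camera adjusted p = 1.42e-10, and 0.385 with an estimated correlation). After subtraction of other tissues' shares 25 of them rose. Both contrasts use the same 3 TC libraries, so neither this rise nor the 470 shared calls are separate evidence. Brain-enriched unigenes moved down, with 12 falling and 1 rising (median -0.13, camera adjusted p = 3.07e-07, and 0.607 with an estimated correlation). The 1096 calls became 4 at a pseudocount of 0.1, 145 with no filter, 132 with the 5 FPKM filter, 1786 in a fit of TC and T alone, and 0 with voom. They were 2510 and 678 without healthy libraries 1 and 3, 2, 12 and 6 without T libraries 4, 5 and 6, and 350, 10 and 1 without TC libraries 7, 8 and 9. TRINITY_DN54786_c2_g2, TRINITY_DN45401_c1_g2 and TRINITY_DN66054_c0_g1 were called without any 1 healthy library and lost the call without any 1 of the 6 T and TC libraries 4 to 9 (limma adjusted p 0.0679 to 0.157). TRINITY_DN60553_c2_g1 was called in all 9 such fits.

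T brain differed little from healthy brain. TRINITY_DN70418_c6_g1 was the 1 unigene called, at 0 counts in T (limma adjusted p = 0.00301), and 0 unigenes were higher. It was not called at a pseudocount of 0.1, with the 5 FPKM filter or with voom (limma adjusted p = 0.121, 0.634 and 0.764), and fell below the filter without any 1 healthy library. Without healthy libraries 1, 2 and 3 there were 4, 1 and 4 calls, all higher in T and none of them this unigene. It stayed called without any 1 T or TC library, with counts of 6 without T library 5 and 5, 10 and 3 without TC libraries 7, 8 and 9, and the fit of T and H alone called 12 (4 higher and 8 lower). At an unadjusted p below 0.05 there were 6221 unigenes (6.62%), of which 5109 were lower. Liver-enriched unigenes had a median log2 change of 0.02, unigenes even across tissues 0.15 and muscle-enriched ones -0.01, against -0.15 for all unigenes, and all 3 groups passed camera at the preset correlation (adjusted p = 1.47e-05, 9.89e-14 and 0.0062) but not with an estimated one (adjusted p = 0.52, 0.507 and 0.581 with an estimated correlation). Brain-enriched unigenes had a median of -0.20 (camera adjusted p = 0.0806). The test of any difference among the 3 health states called 594 brain unigenes. That number was 8 at a pseudocount of 0.1, 116 with no filter, 2 with the 5 FPKM filter and 0 with voom, and ranged from 11 without healthy library 3 or TC library 9 to 2279 without healthy library 1, with 30 to 105 without any 1 of the other 6.

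Liver showed 1 called unigene in either diseased state. TRINITY_DN44822_c3_g1 (1044 bases) fell from 10.1 ± 4.15 FPKM in healthy liver to 0.0933 ± 0.0817 in T and 0.175 ± 0.0788 in TC liver (SD, n = 3), with 1142, 11 and 20 counts, a log2 change of -3.28 ± 0.325 (SE, limma adjusted p = 0.0331) in T and -3.18 ± 0.325 (limma adjusted p = 0.0454) in TC. It was also the 1 unigene called by the test of any difference. Liver-enriched unigenes stood higher relative to the rest in T (median 0.15 against -0.32; camera adjusted p = 6.54e-16; adjusted p = 0.112 with an estimated correlation; exact permutation p = 0.643 over the 3 states). In TC their median was -0.10 against -0.29, so the camera test pointed up although the median was below 0 (adjusted p = 4.75e-06; adjusted p = 0.259 with an estimated correlation). Muscle-enriched unigenes stood lower in T liver (median -0.71; camera adjusted p = 0.0182; adjusted p = 0.777 with an estimated correlation). Unigenes even across tissues stood higher than the rest in TC against H (median -0.10; camera adjusted p = 0.0189) and in TC against T (median 0.20; camera adjusted p = 0.0062), with adjusted p = 0.8 and 0.777 with an estimated correlation. Brain-enriched unigenes did not pass in any of the 3 contrasts (camera adjusted p = 0.278, 0.834 and 0.517).

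In liver 3351 unigenes had an unadjusted p below 0.05 in T against H, 5680 in TC against H (14.2%, of which 4850 were lower) and 2371 in TC against T, where limma called 0. The median of all unigenes was -0.31 in T minus H and -0.28 in TC minus H as deposited, and lay within 0.03 of 0 after rescaling, so group changes are given relative to the other unigenes. Healthy library 1 weighed most: without it 793 unigenes were called in TC minus H (195 higher and 598 lower), 28 in T minus H and 227 in the test of any difference, and without TC library 9 they were 121, 0 and 5. All 3 counts were 0 without healthy library 3 or T libraries 4, 5 or 6, and T minus H was also 0 without TC library 7. TC minus T gave 1, 1 and 4 without healthy library 3 and TC libraries 7 and 9. TRINITY_DN44822_c3_g1 fell below the filter without any 1 healthy library. Its fall in T was not called without T libraries 4, 5 and 6 or TC libraries 7, 8 and 9 (limma adjusted p = 0.336, 0.394, 0.444, 0.0968, 0.0705 and 0.14). Its fall in TC was called without TC library 9 (limma adjusted p = 0.0352) and not without libraries 4 to 8 (0.189, 0.211, 0.19, 0.131 and 0.209). With voom 0 liver unigenes were called in any comparison.

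Muscle had 0 called unigenes in every comparison with limma, and also 0 with voom. Without healthy library 2 there was 1 in T minus H, in TC minus H and in the test of any difference, without TC library 7 there were 2, 0 and 2 and 1 in TC minus T, and without TC library 8 there was 1 in T minus H. Unadjusted p-values below 0.05 numbered 1408 in T minus H (4.95%), 1715 in TC minus H (6.02%), 1300 in TC minus T (4.57%) and 1430 in the test of any difference. Muscle-enriched unigenes were low relative to the rest in TC (median -0.15 against 0.26 in TC minus H; camera adjusted p = 1.24e-12; adjusted p = 0.112 with an estimated correlation), and likewise in TC minus T (median -0.20; camera adjusted p = 7.47e-07; adjusted p = 0.248 with an estimated correlation). In T minus H they had a median of 0.05 against 0.18 (camera adjusted p = 0.0223, and 0.581 with an estimated correlation). After subtraction of other tissues' shares the median was still 0.05 (camera adjusted p = 0.057, without the intensity trend). The higher p-value thus cannot be credited to the subtraction alone. Unigenes even across tissues were high in T minus H (median 0.54; camera adjusted p = 1.7e-07) and TC minus H (median 0.44; camera adjusted p = 0.0022), with adjusted p = 0.777 and 0.876 with an estimated correlation. Brain-enriched unigenes did not pass in any of the 3 contrasts (camera adjusted p = 0.536, 0.823 and 0.413).

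Liver-enriched unigenes in muscle passed camera in all 3 contrasts as deposited. Their medians were 0.81 in T minus H, 0.59 in TC minus H and -0.26 in TC minus T (adjusted p = 2.93e-16, 0.0365 and 3.77e-10; adjusted p = 0.404, 0.876 and 0.52 with an estimated correlation). The liver share of T library 6 was 0.645%, and after subtraction of the shares 0 of these 3 tests passed (camera adjusted p = 0.0777, 0.566 and 0.213). The group medians were then 0.251, 0.313 and 0.025, and these camera tests also left out the intensity trend. The mean log2 level of the group was 1.5 ± 0.262 in H, 2.63 ± 0.614 in T and 2.1 ± 0.705 in TC muscle (SD, n = 3; exact permutation p = 0.111).

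The difference between TC and healthy frogs was itself compared between tissues. It differed between brain and liver in 218 of 20468 unigenes, of which 217 changed more upward in brain. Those 217 had a median log2 change of 0.72 in brain and -1.63 in liver, and 26 of them were called in brain. TRINITY_DN70077_c0_g1 was at 5.29 ± 8.26 and 23.2 ± 12.9 FPKM in H and TC brain and at 61.3 ± 9.86 and 14.3 ± 7.77 in H and TC liver (SD, n = 3; difference 4.90 on the log2 scale, limma adjusted p = 0.0183). TRINITY_DN74954_c5_g1 was at 9.27 ± 5.28 and 35.5 ± 19.8 FPKM in brain and 42 ± 46.9 and 3.54 ± 3.54 in liver (difference 4.71, limma adjusted p = 0.0163). Between liver and muscle 33 unigenes differed, all more downward in liver, with a median of -2.08 in liver and 0.50 in muscle, and 25 of them were among the 217. Their median FPKM was 737 in liver and 1350 in brain. TRINITY_DN64736_c7_g2 was at 3984 ± 1822 FPKM in healthy and 300.2 ± 20.8 in TC liver, and at 332 ± 134 and 469 ± 119 in H and TC muscle (difference -4.15, limma adjusted p = 0.0173). TRINITY_DN71737_c0_g6 was at 30.3 ± 17.4 and 1.38 ± 0.684 FPKM in H and TC liver (difference -3.81, limma adjusted p = 0.00291).

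With limma brain and muscle differed in 0 unigenes and 1311 had an unadjusted p below 0.05; voom was not run on tissue differences. After median-of-ratios rescaling the 218 became 56 (51 higher and 5 lower in brain), the 33 became 0 and the 18 called by the test of any interaction became 0. On the deposited scale that test had 2297 (11.2%) unigenes at an unadjusted p below 0.05. With the library number as a block, which pairs all 3 tissues, 649 unigenes differed between brain and liver (644 higher and 5 lower in brain), among them all 218. Without library numbers 2 or 8 the brain and liver count was 0, and it was 512, 24, 72, 105, 57 and 517 without numbers 1, 3, 5, 6, 7 and 9. The test of any interaction gave 269 and 169 without numbers 1 and 9, 8 without number 7, and 0 without 2, 3, 5 or 8. The liver and muscle count was 758, 14, 19, 16, 63 and 203 without numbers 1, 2, 3, 7, 8 and 9, and the brain and muscle count was 6 without number 1.

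Finally, the changes in T and in TC were compared with each other, both being measured against the same 3 healthy libraries. Across unigenes the log2 changes correlated at r = 0.308 in brain, 0.515 in liver and 0.495 in muscle, where unchanged groups against shared controls gave 0.4995, 0.501 and 0.5005 in simulation. The covariance exceeded the simulated one by 0.043 in liver, and was below it in brain (difference -0.0089) and muscle (difference -0.0046). TRINITY_DN70418_c6_g1 in brain and TRINITY_DN44822_c3_g1 in liver were called in both T and TC and were lower in both, which unigenes high by chance in the healthy libraries would also be. The 3 healthy libraries do not make separate sets of at least 2, so they were not split, and part of the excess in liver may come from the shared healthy libraries.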

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

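The regroupings of libraries were planned before the counts were seen, and leaving out library numbers and rescaling in the tissue pairs were added afterwards. The response to health state differed between tissues in 3 tests of the difference itself on the deposited FPKM scale. The test of any interaction called 18 unigenes, and 3 of 100 regroupings of the library numbers over the health states gave as many, the real one included. That share is under 5%, but it was not adjusted for the other tests of splits, so it argues against chance only weakly on that scale. After median-of-ratios rescaling 0 unigenes were called. On the deposited scale 1 regrouping gave 415. Whether a structure of the libraries that the health states do not describe gave that count was not tested.

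TC minus H differed between brain and liver in 218 unigenes, 217 of them more upward in brain. The highest of the other 99 regroupings gave 45, so 1 of 100 gave as many. Every regrouping kept library number 1 in H and never put number 2 in TC. The regroupings therefore cover only some of the assignments that TC minus H can take, and chance is not excluded for the pairs of tissues. After rescaling 56 were called (51 higher and 5 lower in brain), 52 of them among the 218. The 217 were lower in TC than in healthy liver in all 217 cases and higher in TC brain in 209. TC minus H differed between liver and muscle in 33 unigenes, and the highest of the other regroupings gave 31 (1 of 100 gave as many), but 0 were called after rescaling. Regroupings were not run on rescaled values. Without library number 1 these counts were 512 and 758, and without numbers 2 and 8 the first was 0. Between brain and muscle 0 unigenes differed, which all 100 of 100 regroupings matched, and the highest other gave 1. The test of any interaction and the difference between liver and muscle therefore depend on how the libraries are scaled. Subtraction of other tissues' shares, also added afterwards, left 19, 218 and 35 calls, of which 18, 215 and 33 were among the 18, 218 and 33. Carried RNA at 1 share per library and source tissue therefore does not account for these counts. No biological explanation was tested.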

How the results depend on the processing

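Voom, the subtraction of other tissues' shares, the tests of unigene groups, rescaling in the tissue pairs and the leaving out of library numbers were chosen after the data were seen. The preset gene list tests and their 3 alternatives were not run, since the table names no genes. The counts moved by over 1.5 times as follows, and the cause was not tested. In brain the test of any difference went from 594 to 8 at a pseudocount of 0.1, 116 with no filter, 2 with the stricter filter and 0 with voom. T minus H went from 1 to 0 at a pseudocount of 0.1, with the stricter filter and with voom, and to 12 in the 2-group fit. TC minus H went from 689 to 17, 151, 10, 0 and 40 under pseudocount 0.1, no filter, stricter filter, voom and 2-group fit. TC minus T went from 1096 to 4, 145, 132, 0 and 1786. In liver the test of any difference, T minus H and TC minus H went from 1 to 0 at a pseudocount of 0.1, with the stricter filter and with voom. Liver TC minus H was also 0 after rescaling and in the 2-group fit and 2 with no filter. The interaction went from 18 to 285 with no filter and 0 after rescaling, which took brain against liver from 218 to 56 and liver against muscle from 33 to 0. With the library number as a block it was 71, brain against liver went from 218 to 649, and liver against muscle from 33 to 108, while brain against muscle kept 0. For brain with muscle and liver with muscle 6 of 9 correlations exceeded 0.1 (r from 0.026 to 0.28 and from -0.0645 to 0.297). Among the 3 libraries of the same state, 8 and 7 of 9 correlated best with their own number, so the numbers may pair muscle too.

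Leaving out 1 library gave 11 to 2279 for any difference in brain, 1 to 10 for T minus H, 11 to 2270 for TC minus H and 1 to 2510 for TC minus T. In liver the ranges were 0 to 227, 0 to 28, 0 to 793 and 0 to 4, and in muscle 0 to 2, 0 to 2, 0 to 1 and 0 to 1. Without 1 library number the interaction ranged from 0 to 269, brain against liver from 0 to 517, brain against muscle from 0 to 6 and liver against muscle from 14 to 758. In muscle all other alternatives gave 0. Subtraction of other tissues' shares kept all 16 counts within 1.5 times, and rescaling 12 of 16. At a pseudocount of 0.1 the correlations of the T and TC changes were 0.352 in brain, 0.48 in liver and 0.507 in muscle.

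Of the 11 named changes, 0 passed with voom, 3 at a pseudocount of 0.1, 2 with the stricter filter, 7 with no filter, 7 in the 2-group fit, 10 after rescaling and 10 after subtraction, all in the same direction. Without any 1 of the 3 healthy libraries of its tissue TRINITY_DN70418_c6_g1 in brain and TRINITY_DN44822_c3_g1 in liver fell below the filter and gave no value. Of the 36 group tests 22 passed after rescaling, but muscle unigenes even across tissues no longer did in TC minus H (adjusted p = 0.0614, limma) and newly did in TC minus T (adjusted p = 0.0207). Rescaling moved the median of all unigenes by 0.14 in brain T minus H, 0.31 and 0.25 in liver T and TC minus H, and -0.18 and -0.26 in muscle. In the camera tests after subtraction of other tissues' shares, 4 of the 22 group tests no longer passed. Those tests also left out the intensity trend, so changed calls there cannot be credited to the subtraction alone. Muscle-enriched unigenes newly passed in liver TC minus T (higher, camera adjusted p = 0.0189). Unigenes even across tissues newly passed in muscle TC minus T (lower, camera adjusted p = 0.0472). Depth was similar in all libraries, at 31340952 to 37806798 counts.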

Other observations

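The liver transcripts in TC brain, the place of healthy library 1 and the unigenes read in 1 state were noticed, and their tests chosen, after results were seen, while the splits of libraries were planned earlier. Abundance in liver was set against change in TC brain. The 5 liver-enriched unigenes most abundant in liver, at 28500 to 39580 FPKM there, were at 0.0699 to 0.264 FPKM in healthy brain, 0.671 to 1.2 in T brain and 4.53 to 18 in TC brain. Of the 917 liver-enriched unigenes 252 were not higher in TC than in healthy brain, among them 0 of the 100 most abundant, whose median share of the liver level was 0.0875%. The median over the 917 was 1.63%. All 917 had passed the brain filter, and the 100 had medians of 0.241 FPKM in healthy and 9.97 in TC brain. A member near 0 in healthy brain could pass through the TC libraries alone, which fixes its direction. The 100 most abundant liver-specific unigenes, chosen without that filter, were also all higher in TC than in healthy brain.

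For the 100 most abundant liver-specific unigenes, a candidate explanation is liver RNA or reads carried into the TC brain libraries. Of the 100, 66 lay within 3 times of their median share, which met a cutoff chosen after the data were seen. The interquartile ranges of the share were 0.0289 to 0.195%, 0.023 to 0.067% and 0.052 to 0.104% in TC brain libraries 7, 8 and 9. No set without a carried source was measured for comparison, so the count does not decide whether 1 source gave these transcripts. Whether the liver library of the same number was the source stays open, since the log2 ratios between TC libraries correlated between liver and brain at 0.686, 0.466 and 0.212 for the 3 pairs of numbers. For the whole group carried liver RNA is argued against: 56 of the 100 most abundant rose by less than 0.1 of the median share of 1.63%, at which the top 5 would stand far above the 18 FPKM measured. Scaling of the libraries is argued against too. After rescaling the mean log2 level of the group was 2.48 ± 0.435 in H and 3.45 ± 0.179 in TC brain (SD, n = 3), a difference of 0.973. On the deposited scale camera did not pass with an estimated correlation (camera adjusted p = 0.177), and that test was not run on rescaled values. A change in the TC brain itself remains open for the 817 less abundant members, as does RNA of another cell type, for which no marker genes could be named.

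Healthy library 1 lay toward TC in all 3 tissues. Its deviation from healthy libraries 2 and 3 was correlated across unigenes with TC minus T, which uses none of these libraries. The correlation was 0.364 in brain, 0.364 in liver and 0.243 in muscle. Healthy library 2 lay the other way, at -0.308, -0.355 and -0.293, and library 3 was at -0.095, -0.189 and -0.0496. Each deviation is taken from the other 2 healthy libraries, so the 3 deviations sum to 0. A library 2 that lies away from TC would thus also give library 1 positive values. A role of scaling is not decided: 1 factor per library shifts its unigenes nearly alike and hardly moves such a correlation (lowest value 0.249 after rescaling). An exchange of a healthy and a TC brain library is argued against, since 0 of 3 TC brain libraries were closer to healthy libraries 2 and 3 than to each other. The lowest correlation of library 1 was 0.2435, as part of the TC profile in its frog would give. Library 2 lying away from TC would give it too, so the values do not decide between them. If the number marks 1 frog, the 3 tissues are 1 observation. Part of the TC profile in the frog of healthy library 1 stays a hypothesis, and sex, age or handling of that frog were not tested.

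Some unigenes had at least 10 counts in every library of 1 health state and 0 in the other 6 libraries of the tissue, or the reverse. In brain there were 28, of which 18 were read in TC, 6 in H and 2 in T alone, and 2 were missing in TC alone. Of the 280 splits into 3 groups 14 gave as many and the highest other gave 41, so chance is not excluded. In liver 3 were found, as many in 252 splits (highest other 25), and in muscle 4, as many in 121 (highest other 11). Whether the frogs differ in a way that every tissue carries, such as a gene variant, stays open: of the 10 that liver also read 1 (10%) separated the same state there, but 10 are few and a rule of 10 counts in each library can miss the pattern where liver reads less, as for TRINITY_DN70418_c6_g1 (9, 44 and 14 counts in healthy liver and 0 in the 6 T and TC livers).

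Other splits of the 9 libraries of each tissue were tried for every count. In brain 594 unigenes differed among the 3 states, 3 of 100 splits gave as many, and the highest other gave 714. That share is under 5%, but it was not adjusted for the other tests of splits, so it argues against chance only weakly. In liver 44 of 100 splits gave as many as the 1 call (highest other 61), and in muscle all 100 of 100 matched 0 calls (highest other 1241), so chance is not excluded there. The 3-against-3 contrasts allow 10 splits, too few for a share under 5%. In brain TC minus H gave 689 against at most 11 in the other splits (1 of 10 as many), TC minus T gave 1096 against at most 6 (1 of 10), and T minus H gave 1 against up to 13 (8 of 10). In liver T minus H, TC minus H and TC minus T the calls were 1, 1 and 0 against up to 6, 35 and 3 (5, 4 and 10 of 10 as many), and in muscle 0, 0 and 0 against up to 18, 2 and 6 (10 of 10 each). The splits with 61, 35, 18, 13 and 1241 calls exceeded the real count several times, but they are the highest of the other splits. Whether structure among the libraries other than health state gave them was not tested.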
